A study of Apis mellifera with 176 samples.

How the data were processed

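RNA from the upper midbrain of 176 single worker bees was made into stranded polyadenylated RNA libraries from 550 ng of RNA, with less in 19 samples, and sequenced as single reads of 100 nt, per the labels' protocols. Reads were handled with CASAVA 1.8.2, TopHat2 2.0.10, Bowtie2 2.1.0, SAMtools 0.1.18 and HTSeq 0.6.1, per the submitters' processing notes, which give no order or settings. The genome build is Amel 4.5, per the labels. The strand setting of the counting and the gene set are not given in the sources used here, so that overlapping and antisense genes, and genes with close copies, can share or lose reads.

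The deposited files hold whole-number counts of reads per gene, 1 file per bee, with 15314 gene identifiers and 5 summary lines that name no gene. The gene counts, reads in no gene, ambiguous reads and the labels' multiply aligned reads added up to the labels' mapped reads in 176 of 176 libraries. The summary line for reads that were not unique was not part of this sum. The summary lines were left out of library sizes and tests. Shares were taken of the gene counts and summary lines added together, a total that differs from the mapped reads. By this measure a median of 28.4% lay in no gene (23.5 to 46.2%). A median of 0.221% were ambiguous and 2.65% were not unique, with a maximum of 7.73%. No count was normalised before deposition as far as the values show, since gene totals differed between libraries from 3.19 to 20.4 M (mega-reads).

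None of the gene identifiers was found in the reference gene table used here (0 of 15314 against 12398 genes of assembly Amel_HAv3.1), and the files pair them with no names. Gene lists and markers of other tissues fixed before the data were examined could therefore not be matched to the counts, and their tests were not run. Genes fixed to be reported whatever the result could not be looked up either. By a rule fixed before the data were examined, at most 2 identifiers that rose and 2 that fell are named for each nurturance comparison, those with the smallest p past the threshold and the same sign in each colony. For the other tests the 2 with the smallest p are named.

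Samples were grouped by treatment, time and colony from the labels. Counts were filtered by edgeR's filterByExpr over the 18 groups, which left 11314 genes (11180 for the nurturance bees alone), scaled by TMM, and tested with edgeR 4.0.16 (R 4.3.3) by robust quasi-likelihood fits with 1 mean per group and 158 residual degrees of freedom. Contrasts averaged the colonies with equal weight, and p-values were two-sided and adjusted by Benjamini-Hochberg over the tested genes, with a threshold of 0.05. Differences between times or colonies were F tests over the contrasts. Where 0 genes passed, the number at an unadjusted p under 0.05 is also given. With no effect about 0.05 of the tested genes would lie there, so such a number is by itself no sign of a response. Time in the queen cell entered as a slope per 10 s with a mean for each time and colony. Standard errors of fold changes were taken as the absolute log2 fold change over the square root of F. CPM was computed here from the counts with TMM library sizes, and log2 CPM with a prior count of 2.

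The number of the behavioural replicate pairs nurturance and control bees, per the labels. The numbers formed 75 exact pairs, 26 bees had no exact partner, and 10 control numbers carried a letter suffix. Deviations from the group means correlated with a median of 0.0852 within pairs and -0.0181 between unpaired bees of the same time and colony, and 33 of 75 pairs were over 0.1. The unblocked fit on all bees was fixed as the main one before the data were examined, and blocked fits as alternatives. It was kept although in edgeR each blocked fit gave fewer genes than the same bees without a block, or as many. The random effect for the pair was fitted in limma-voom, where it gave more genes than no block, or as many. No pair of libraries held counts within sampling noise: over all 15400 pairs the lowest chi-square per degree of freedom was 4.53, over the 774 pairs within groups 5.04, and over the pairs with nurturance bee 103, a check added after its levels were seen, 6.23.

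Libraries whose median correlation with the others lay more than 6 median absolute deviations below the median were set apart. This threshold, the SD of 1 for genes of high spread, the 1.5-fold division, the modules of genes, the lane-label term, the fits to paired bees without a block and the fits without single libraries were chosen after seeing the data. Further alternatives fixed before were the size factors of DESeq2 1.42.0 and its Wald test, no filter, limma-voom (limma 3.58.1), single colonies or lane labels left out, and 2 surrogate variables (sva 3.50.0). Permutations used Python 3.11.15 with NumPy 2.4.6, and plots matplotlib 3.10.9.

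The fits were tested on simulated counts with the means and library sizes of these bees, with 50 genes changed at each of the fold sizes 1.25, 1.5, 2 and 4. The simulated spread followed the trend with abundance alone. It held no differences in spread between genes of like abundance, no genes of high spread and no libraries that stand apart. The shares below hold for that simpler spread. At 30 min 56% of genes changed 1.25-fold, 92% at 1.5-fold, 98% at 2-fold and 100% at 4-fold were recovered. For the mean of times the shares were 86, 100, 100 and 100%. False calls made up 6.49% of calls at 30 min, 1.16% at 60 min, 5.06% at 120 min and 5.39% for the mean. The submitters' screen for Deformed Wing Virus, a common bee virus, excluded samples at a share of reads of 0.005, and the highest share in the labels was 1.24e-06, with 32 reads in a control bee and at most 23 in a nurturance bee.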

Results

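Brains of honey bee workers (Apis mellifera) were profiled one bee at a time after an encounter with a queen larva. Workers 7 days old were given a queen larva 4 days old in a wax queen cell for 5 min, and the upper midbrain, which holds mostly the mushroom bodies (paired insect brain centres for learning and sensory integration) and the central brain, was sequenced as polyadenylated RNA. The 88 bees with this contact are called nurturance bees below, and 88 control bees were taken at matched times; the labels do not say what the control bees were exposed to. Bees were collected 30, 60 or 120 min later, 58, 60 and 58 bees, from 3 colonies (R02 with 60 bees, R40 with 60 and R41 with 56). Each colony had a queen inseminated by 1 drone, so that the workers of a colony are close sisters. The 18 groups of treatment, time and colony held 9 or 10 bees each. Each library is a separate bee, so the p-values below measure the spread between bees within a group. They do not measure the spread between colonies, of which there are 3.

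Reads counted in genes ranged from 3.19 to 20.4 M (mega-reads) per library, with a median of 13.1 M, and 11314 genes were tested. Nurturance libraries held 13.6 ± 2.58 M reads in genes and control libraries 12.9 ± 2.54 M (SD, n = 88 each). The fitted biological coefficient of variation between bees of a group was 21.2%. Of the nurturance bees, the time spent inside the queen cell averaged 77.9 ± 24.8 s (SD, n = 88), with a range of 45 to 169 s. The index sequences of the libraries were not shared between the treatments (0 of 12 i7 sequences), so index and treatment cannot be separated. A single lane label covered all bees of colony R41 and 16 of the bees of colony R02 at 120 min. It is read here as merged lanes, a meaning the labels do not state. It leaves colony R41 and the lane label confounded, while nurturance and control bees were balanced over it. The genes carry identifiers that match none of the names in the reference gene table used here, so results are given by identifier and counts, and no function is attached to any of them.

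In 6 libraries the profile stood apart from the rest, with a median correlation of log2 CPM (counts scaled to a common library size) with the other libraries between 0.780 and 0.958, against 0.966 to 0.982 in the other 170. They were control bees 123 (R02) and 158 (R41) at 60 min, nurturance bees 017 (R40) and 059 (R41) at 30 min, and nurturance bees 223 and 231 (both R02) at 120 min. Their reads in genes numbered 3.19 to 12.5 M. The share of reads mapped was 66.5, 72.2 and 76.7% in bees 158, 017 and 059, against 77.8 to 86.2% in the other 170, and 10349, 11219, 11796 and 11850 genes were detected in bees 158, 017, 059 and 123, against 12056 to 12647. Counts of genes are also given without these libraries for most comparisons below, a comparison added after seeing the data. Nurturance bee 103 at 60 min, labelled R40, had the gene levels of colony R02, with a correlation of 0.900 with the control mean of R02 and -0.0684 with that of R40 over 200 genes that differed between colonies. The other 175 bees resembled the colony on their label most. This bee was kept under its label, and fits without it are given where they differ.

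**Figure D1:**
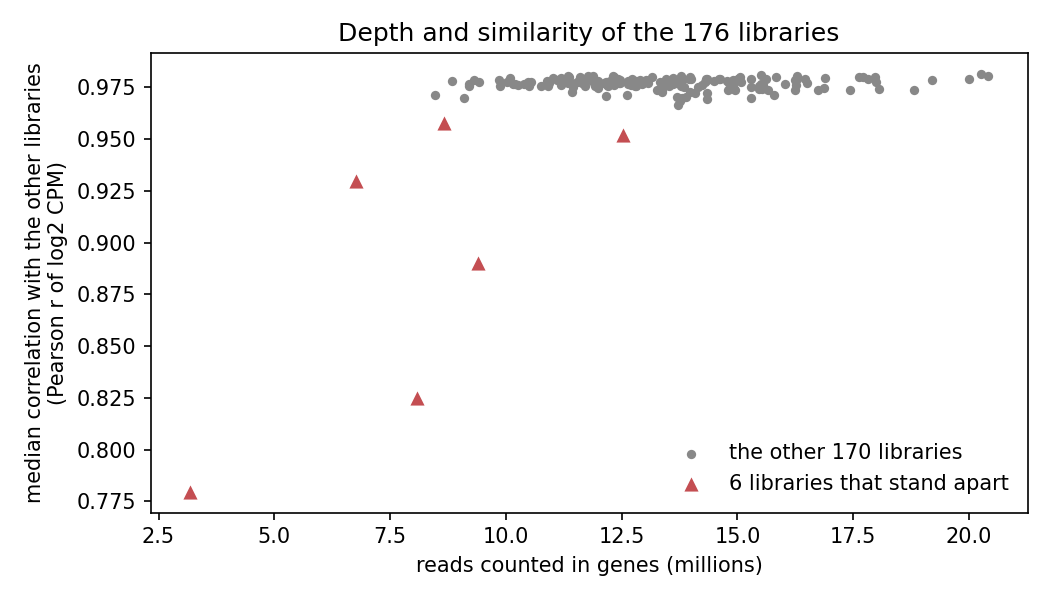
Reads counted in genes (x axis, M) and median Pearson correlation of log2 CPM with the other libraries (y axis) for each of the 176 libraries, with the 6 that stand apart as triangles. The triangles lie between 0.780 and 0.958, below all of the other 170 libraries, whose lowest value is 0.966.

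The broadest comparison asked which genes differed between nurturance and control bees on average over the 3 times and 3 colonies. GB40074 rose the most clearly: it averaged 139 ± 46.7 CPM in nurturance bees and 86.2 ± 36.5 CPM in control bees (SD, n = 88 each), a log2 fold change of 0.69 ± 0.0721 (SE) or 1.61-fold, and was higher in the nurturance bee of 59 of 75 pairs. It was raised by 0.80 on the log2 scale in colony R02, 0.81 in R40 and 0.45 in R41 (adjusted p = 2.95e-13 for the mean, edgeR quasi-likelihood test). GB49295, a gene of low abundance, rose from 1.68 ± 0.957 to 2.99 ± 1.41 CPM, a log2 fold change of 0.80 ± 0.111 (SE), and was higher in 57 of 75 pairs (adjusted p = 1.14e-07). GB53411 fell from 4.41 ± 1.29 to 3.67 ± 1.23 CPM, a log2 fold change of -0.27 ± 0.0664, and GB40107 from 21.9 ± 2.20 to 20.6 ± 1.94 CPM, a log2 fold change of -0.09 ± 0.0214 (adjusted p = 0.0197 and 0.024). The nurturance bee was higher in 18 of 75 pairs for GB40107 and in 27 for GB53411.

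In this comparison 72 genes passed an adjusted p of 0.05, 69 higher and 3 lower in nurturance bees, and 71 of the 72 had the same sign in each colony. The genes were chosen on the mean of these same colonies, which favours like signs. Of the 72, 45 were under 1.5-fold and 21 over 2-fold, and the 69 that rose had a median log2 fold change of 0.36. Among those that rose, 22 were genes of high spread, whose log2 CPM had an SD above 1 between control bees, as 188 of the tested genes did, and these 22 had a median log2 fold change of 1.82, against 0.25 for the other 47. Without the 6 libraries that stand apart 118 genes passed, 99 higher and 19 lower, and 65 of the 72 were among them. Of the 118, 91 were under 1.5-fold and 21 were genes of high spread, and the 99 had a median log2 fold change of 0.23. The labels pair nurturance and control bees by behavioural replicate, and with the replicate as a block 20 genes passed over 75 exact pairs, against 35 for the same bees without a block, and 46 over 85 pairs with a letter suffix on the control number dropped, against 56. Limma-voom gave 40 genes on all bees, 37 higher and 3 lower, and 45 with a random effect for the pair. Without colony R02 17 genes passed and without R40 13, all higher, and a fit with 2 surrogate variables gave 119, 95 higher and 24 lower. With the exact block GB53411 and GB40107 missed the threshold at log2 fold changes of -0.28 and -0.08 (adjusted p = 0.154 and 0.113), as they did in the same bees without a block (adjusted p = 0.0614 and 0.211). Both passed with the suffix dropped (adjusted p = 0.0311 and 0.0407) and in limma-voom without (adjusted p = 0.028 and 0.0329) and with the random effect (adjusted p = 0.0184 and 0.0218). In fits to fewer bees GB53411 missed the threshold without R02, R40 or R41 at -0.29, -0.24 and -0.28 (adjusted p = 0.22, 0.54 and 0.0626), and GB40107 without R02 or R40 at -0.08 in each (adjusted p = 0.464 and 0.427). In single-lane libraries GB53411 stood at -0.31 (adjusted p = 0.248) and GB40107 at -0.09 (adjusted p = 0.394), and in merged-lane libraries at -0.23 and -0.07 (adjusted p = 1 for both). Single-lane libraries gave 17 genes and merged-lane libraries 0 (359 at an unadjusted p under 0.05), with log2 fold changes of 0.42 for GB40074 and 0.53 for GB49295 in the latter (adjusted p = 1 for both). With no effect about 0.05 of the tested genes would lie under an unadjusted p of 0.05. Such counts, here and below, are therefore no sign of a response by themselves.

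**Figure D2:**
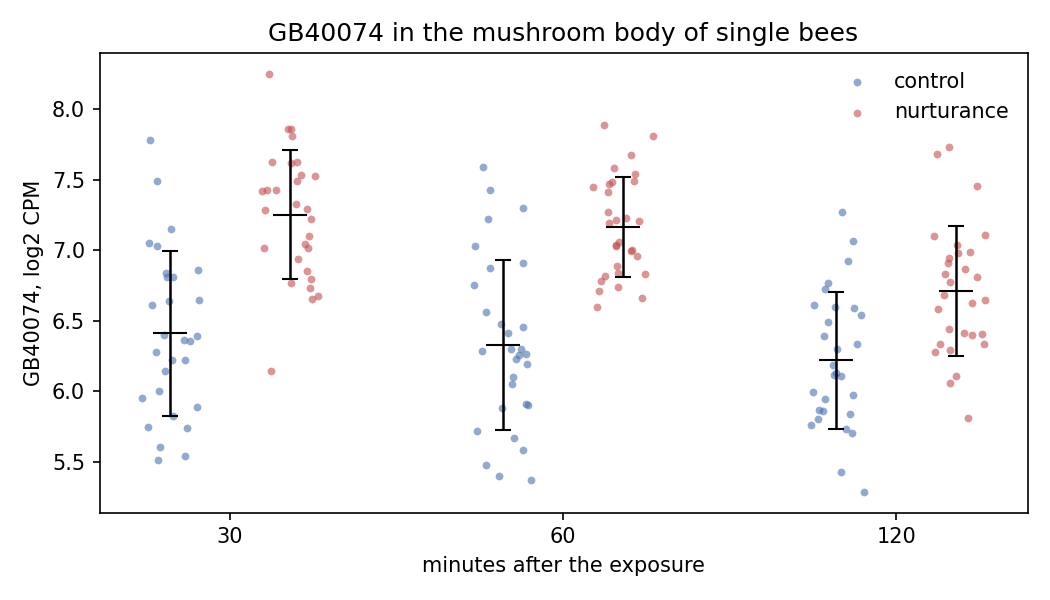
Level of GB40074 (y axis, log2 CPM) in single bees at 30, 60 and 120 min (x axis), control bees in blue and nurturance bees in red, with bars for the mean ± SD of each set of 29 or 30 bees. The means were 6.41 and 7.25 at 30 min, 6.33 and 7.16 at 60 min, and 6.22 and 6.71 at 120 min, control first.

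At 30 min, the earliest time, the genes that passed in the fit to all bees were higher in nurturance bees. GB40074 stood at 160 ± 50.3 CPM against 92.25 ± 40.7 (SD, n = 29 each), a log2 fold change of 0.80 ± 0.126 (SE), and was higher in 22 of 27 pairs (adjusted p = 1.81e-05). GB49756 rose from 46.0 ± 6.72 to 58.1 ± 13.8 CPM, a log2 fold change of 0.33 ± 0.0587, and was higher in 23 of 27 pairs (adjusted p = 0.000435). In all, 17 genes passed, 17 higher and 0 lower, with a median log2 fold change of 0.85, and 5 of them were genes of high spread. Without colony R40 0 genes passed (394 at an unadjusted p under 0.05), and GB40074 stood at 0.69 (adjusted p = 0.562) and GB49756 at 0.20 (adjusted p = 0.974). Without R02 the value of GB40074 was 0.60 (adjusted p = 0.255) and 1 gene passed, and without R41 67 did, 58 higher and 9 lower. The replicate block left 5 genes with exact pairs, against 6 for the same bees without a block, and 6 with the suffix dropped, against 17. Limma-voom gave 7 genes, and 8 with the random effect. The count rested on single libraries: it was 76, 68 higher and 8 lower, without control bee 158 of the 60 min group, 7 without nurturance bee 017 and 6 without nurturance bee 059, and 12 without all 6 libraries that stand apart, of which 8 were among the 17. Those 12 had a median log2 fold change of 0.28, with 9 under 1.5-fold, against 6 of the 17, and 0 of them were genes of high spread. The Wald test of DESeq2 gave 47 genes, 43 higher and 4 lower, while a fit without a filter gave 11, and fits with 2 surrogate variables or with bees of that time alone 8 each, all higher. Single-lane libraries, at this time those of R02 and R40, gave 70 genes, 62 higher and 8 lower. Merged-lane libraries, at this time those of R41 alone, gave 0 (378 at an unadjusted p under 0.05). There the log2 fold change of GB40074 was 0.16 and that of GB49756 0.28 (adjusted p = 0.928 for both). Colony, number of bees and lane label cannot be separated in these fits.

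At 60 min genes moved both ways. GB40074 was again higher, 147 ± 37.45 against 87.7 ± 39.5 CPM (SD, n = 30 each), a log2 fold change of 0.77 ± 0.123 (SE) with 21 of 24 pairs in that direction (adjusted p = 4.87e-05). GB42534 rose from 54.3 ± 11.3 to 70.1 ± 10.4 CPM, a log2 fold change of 0.36 ± 0.0626, in 20 of 24 pairs (adjusted p = 0.000168). GB44190 fell from 189 ± 17.1 to 173 ± 10.7 CPM, a log2 fold change of -0.12 ± 0.0260, and GB43823 from a mean of 12.7 ± 24.8 to 4.86 ± 1.68 CPM, a log2 fold change of -1.28 ± 0.267 (adjusted p = 0.00788 for both). The medians of GB43823 were 5.11 CPM in control and 4.44 CPM in nurturance bees, so that its mean difference came from few control bees. With the exact block GB44190 stood at -0.10 (adjusted p = 0.326) and GB43823 at -0.50 (adjusted p = 0.471), and in the same bees without a block at -0.10 and -1.08 (adjusted p = 0.185 and 0.181). GB44190 passed with the suffix dropped (adjusted p = 0.0204) and in limma-voom without and with the random effect (adjusted p = 0.00569 and 0.00418). GB43823 stood at -0.44 with the suffix dropped (adjusted p = 0.309), against -1.29 in the same bees without a block (adjusted p = 0.0137), and at -0.45 in limma-voom without and with the random effect (adjusted p = 0.425 and 0.377). GB44190 missed the threshold without R02 or R41 at -0.14 and -0.12 (adjusted p = 0.0698 and 0.136) and in single-lane and merged-lane libraries at -0.12 and -0.15 (adjusted p = 0.128 and 0.131). GB43823 missed it without R02 or R40 at -1.15 and -1.02 (adjusted p = 0.106 and 0.0614), with 2 surrogate variables at -0.92 (adjusted p = 0.0655), and with bees of that time alone at -1.29 (adjusted p = 0.0854). In merged-lane libraries, at this time those of R41 alone, GB43823 stood at -0.47, GB40074 at 0.66 and GB42534 at 0.38 (adjusted p = 0.581, 0.13 and 0.0934).

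The 60 min comparison passed 66 genes, 25 higher and 41 lower, and 50 of the 66 were under 1.5-fold. Over exact pairs 2 genes passed with the replicate block and 2 for the same bees without it, all higher. With the suffix dropped 22 passed with the block, 16 higher and 6 lower, and 100 without it, 21 higher and 79 lower. Limma-voom gave 28 genes, 21 higher and 7 lower, and 32 with the random effect, 23 higher and 9 lower. Bees of that time alone gave 14, 11 higher and 3 lower, a fit without a filter 38, 17 higher and 21 lower, and the Wald test of DESeq2 126, 51 higher and 75 lower. Without the 6 libraries that stand apart there were 55 genes, but 37 were higher and 18 lower, 45 were under 1.5-fold, and 32 of them were among the 66. Left out alone, control bee 123 brought the count to 22 with 15 higher and 7 lower, control bee 158 to 22 with 18 higher and 4 lower, nurturance bee 017 to 476 with 84 higher and 392 lower, nurturance bee 059 to 163 with 46 higher and 117 lower, and nurturance bee 103, whose colony label is in doubt, to 30 with 13 higher and 17 lower. The size factors of DESeq2 gave 97 genes, 27 higher and 70 lower. Without colony R02 6 genes passed, 6 higher and 0 lower, without R40 153, 24 higher and 129 lower, and without R41 5, 3 higher and 2 lower. Single-lane libraries, here those of R02 and R40, gave 6 genes, 4 higher and 2 lower. Merged-lane libraries, here those of R41 alone, gave 17, 1 higher and 16 lower.

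**Figure D3:**
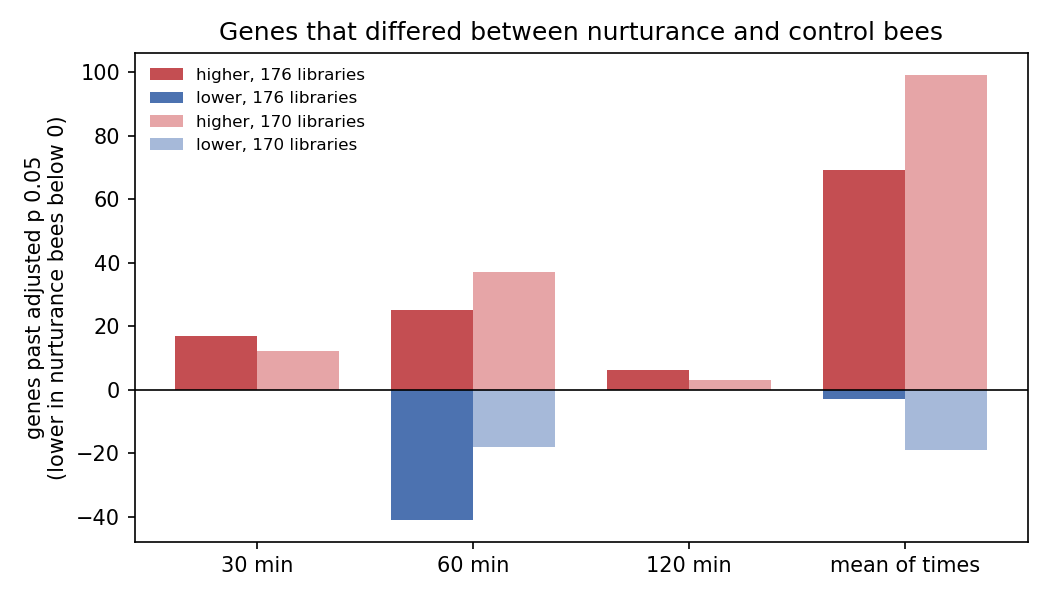
Genes past an adjusted p of 0.05 (y axis, genes lower in nurturance bees below 0) for each time and for the mean of times, with all 176 libraries and with the 170 left without those that stand apart. At 60 min the bars show 25 higher and 41 lower genes with 176 libraries and 37 and 18 with 170.

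At 120 min few genes differed. GB55213 averaged 139 ± 553 CPM in nurturance and 12.7 ± 27.9 CPM in control bees (SD, n = 29 each), with medians of 6.91 and 4.28 CPM, a log2 fold change of 2.69 ± 0.516 (SE) and 19 of 24 pairs in that direction (adjusted p = 0.00643). GB45796 averaged 68.0 ± 225 against 4.86 ± 8.54 CPM, with medians of 0.323 and 0.260 CPM, a log2 fold change of 3.81 ± 0.800 and 14 of 24 pairs (adjusted p = 0.0209). The level of GB40074 was 0.49 ± 0.126 higher on the log2 scale and missed the threshold (adjusted p = 0.0846). The 6 genes that passed were all higher, and 5 were genes of high spread. With exact pairs as a replicate block 0 passed (532 at an unadjusted p under 0.05), against 2 for the same bees without a block, and with the suffix dropped 0 (452), against 4. The exact block gave log2 fold changes of 1.15 for GB55213 (adjusted p = 0.707) and 1.70 for GB45796 (adjusted p = 1), against 2.94 and 3.94 in the same bees without a block (adjusted p = 0.0192 and 0.0695). Without nurturance bee 223 the count was 1, and without it GB55213 had a log2 fold change of 1.69 (adjusted p = 0.27) and GB45796 of 2.30 (adjusted p = 0.589). It was 3 without all 6 libraries that stand apart, of which 1 was a gene of high spread, with GB55213 at 1.74 (adjusted p = 0.148) and GB45796 at 2.37 (adjusted p = 0.309). It was 11 without control bee 123, 16 without control bee 158 and 15 without nurturance bee 231. Leaving out any of the colonies R02, R40 and R41 left 0 genes (297, 531 and 351 at an unadjusted p under 0.05), with GB55213 at 2.14, 3.47 and 2.47 (adjusted p = 0.443, 0.0549 and 0.346) and GB45796 at 3.71, 4.86 and 2.85 (adjusted p = 0.477, 0.0938 and 0.655). Limma-voom gave 0 genes (468), with GB55213 at 0.99 and GB45796 at 0.77 (adjusted p = 0.998 for both), and 0 with the random effect (512). Bees of that time alone gave 5 genes, 4 higher and 1 lower, of which 1 was among the 6. The Wald test of DESeq2 gave 22 genes, 20 higher and 2 lower, and 2 surrogate variables 13, 12 higher and 1 lower. Single-lane libraries gave 2 genes and merged-lane libraries 0 (388 at an unadjusted p under 0.05).

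Whether the response to nurturance differed between times was tested directly. GB49756 was 0.33 ± 0.0587 higher on the log2 scale in nurturance bees at 30 min, against -0.14 ± 0.0576 at 60 min and -0.01 ± 0.0587 at 120 min (SE, adjusted p = 0.00147 for the difference between times). GB43842 stood at 0.09 ± 0.0294, -0.12 ± 0.0288 and -0.05 ± 0.0294 (adjusted p = 0.0134). In all 10 genes passed this test, 2 in limma-voom, and 1 without the 6 libraries that stand apart, where GB43842 had an adjusted p of 0.0521. Taken by pairs of times, 947 genes differed in their response between 60 and 30 min, 866 of them lower at 60 min, and 2 without the 6 libraries. Between 120 and 30 min 0 differed (502 at an unadjusted p under 0.05) and between 120 and 60 min 0 (1293).

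Between colonies the response to nurturance differed for 1 gene. GB46365 averaged 1.27 ± 2.40 CPM in nurturance and 11.1 ± 38.2 CPM in control bees of R02 (SD, n = 30 each), 2.78 ± 10.2 and 0.199 ± 0.278 CPM in R40 (n = 30 each), and 0.797 ± 1.76 and 0.379 ± 0.566 CPM in R41 (n = 28 each; adjusted p = 0.000169 for the difference between colonies). Its median in each of these groups was at most 0.391 CPM, so that the means came from few bees, and limma-voom gave 0 genes (248 at an unadjusted p under 0.05). Tested within single colonies over all times, 27 genes differed between nurturance and control bees in R02, 4 in R40 and 0 in R41 (454 at an unadjusted p under 0.05). These counts were 10, 41 and 0 (616) without the 6 libraries that stand apart, and 1 gene still differed in its response between colonies.

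Control bees alone show how far gene levels shifted over the same interval without the assigned contact. GB47814 stood at 138 ± 19.8, 130 ± 14.7 and 122 ± 14.5 CPM at 30, 60 and 120 min (SD, n = 29, 30 and 29), and GB51535 at 117 ± 22.2, 105.5 ± 12.0 and 98.8 ± 6.51 CPM (adjusted p = 0.00381 for both). In control bees 86 genes differed between times, 54 of them lower and 32 higher at 120 than at 30 min, and the largest such change was 1.06 on the log2 scale. Without the 6 libraries that stand apart 299 genes differed, 217 lower and 82 higher at 120 min, and 59 of them were among the 86. The processing moved the count too, to 131 genes with the size factors of DESeq2, 52 without a filter and 30 in limma-voom. In colony R02 8 of 10 control bees at 120 min carry the merged-lane label and 0 of 20 at the earlier times do, so that time and label are partly confounded there. With a term for the label 107 genes differed, 68 of them among the 86. That term rests on R02 at 120 min alone, so it is imprecise. Within each colony, control bees at 30 and 120 min shared no i7 index sequence, so that time and index cannot be separated there. No fit addressed this.

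Colony of origin separated the bees far more than nurturance or time. In control bees 5444 genes differed between colonies, with 3245 between R40 and R02, 3748 between R41 and R02, and 3241 between R41 and R40, and a median absolute log2 difference of 0.26 in each. When the 6 libraries that stand apart were left out 7935 genes differed, with 5469, 5532 and 5120 between these pairs of colonies and median absolute log2 differences of 0.18, 0.18 and 0.17. GB55143 stood at 88.8 ± 5.09 CPM in R40 (SD, n = 30), 5.71 ± 1.08 CPM in R02 (n = 30) and 6.20 ± 1.52 CPM in R41 (n = 28), without overlap between R40 and the other two (adjusted p = 4.9e-98). Reads of GB45748 were found in 28 of 28 control bees of R41, at 34.6 ± 13.4 CPM, in 8 of 30 of R02 with 12 reads in all, and in 1 of 30 of R40 with 1 read (adjusted p = 1.33e-103). Because all bees of R41 carry the merged-lane label, its differences cannot be separated from that label by the samples of R41 alone. With a term for the label 3274 genes differed. That term rests on the bees of R02 at 120 min alone, where 8 of 10 of each treatment carry the label. Nurturance bees 223 and 231, whose libraries stand apart, are among them. The term is thus imprecise, and the lower count is no measure of lane effects. Between R02 and R40 alone 2697 genes differed in single-lane libraries, against the 3245 in all libraries.

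Among the 88 nurturance bees, gene levels were compared with the time spent inside the queen cell. GB51439 was higher by 0.155 ± 0.0312 and GB43377 by 0.09 ± 0.0178 on the log2 scale per 10 s (SE, adjusted p = 0.0329 for both), and these 2 genes, of 11180 tested, were the only ones to pass, as they were without the 6 libraries that stand apart (adjusted p = 0.0399 and 0.0412). Both differed by colony: in nurturance bees GB51439 stood at 11.3 ± 1.79 CPM in R02 and 0.622 ± 0.256 CPM in R41, and GB43377 at 30.1 ± 3.72 and 4.89 ± 1.28 CPM (SD, n = 30 and 28). Nurturance bee 103, labelled R40 and with the gene levels of R02, had 9.80 CPM of GB51439 and 29.1 CPM of GB43377, against at most 2.44 and 5.90 CPM in the other 29 nurturance bees of that label. Its time of 168 s was the second longest. Without this bee 0 genes passed (526 at an unadjusted p under 0.05), with log2 differences per 10 s of 0.02 for both genes (adjusted p = 0.888 for GB51439 and 0.855 for GB43377). They were also lost without the 2 bees with the longest times, of which it is one (adjusted p = 0.64 and 0.792), and in limma-voom (adjusted p = 0.981 for both), and with log2 of the time 0 genes passed (810 at an unadjusted p under 0.05).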

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

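The tests of reads in no gene and other measures of library quality, of genes chosen without the colony they were tested in, of the 5 libraries that deviate alike, of nurturance bee 223, of the difference between 60 and 30 min, and of genes of high spread without the libraries that stand apart and for shared variation were chosen only after the result was seen. Of 108 checks of the highest and lowest bee of a group of 9 or 10, 11 found a bee far from its group, where chance gives about 1 in 20, or 5.4.

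In reads in genes, control bees 221 (R02, 20.4 M) and 211B (R40, 15.3 M) at 120 min lay above their groups, and control bees 123 (R02, 6.76 M) and 158 (R41, 3.19 M) at 60 min below. The share of reads in no gene was the highest of its group in control bee 158 at 46.2% and in nurturance bee 017 (R40, 30 min) at 36.9%. GB49295 was the lowest of its group in control bee 123 and nurturance bee 017, both at -2.73 log2 CPM, and in nurturance bee 059 (R41, 30 min) at -1.94. GB53411 was the lowest in nurturance bee 223 (R02, 120 min) at 0.99 log2 CPM, and GB40107 the highest in nurturance bee 158 (R41, 60 min) at 4.52. The response to nurturance differed between times for 10 genes, and 2 of 80 regroupings of the bees over times, the real one included, gave as many, with 19 in the highest other. The first 40 drawn also gave 2, a share of 0.05 at which chance is not excluded. More were drawn after this was seen, so the regroupings do not decide. Those over times were not repeated without the 6 libraries that stand apart. The response differed between colonies for 1 gene, and 47 of 100 regroupings over colonies gave as many, with 30 in the highest other, so that chance is not excluded. These regroupings mix bees of colonies that differed in 5444 genes, so their spread is not that of the real groups. They therefore cannot decide either way.

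In 6 libraries the profile stood apart, and in 5 of them, all but nurturance bee 223, the deviations from the group means went alike, with correlations across genes of 0.543 to 0.866. The tables argue against low depth for most of them: group mates thinned to the same totals stayed above the threshold for 5 of the 6, the exception being control bee 158, whose mates reached -6.88 median absolute deviations against its own -76.7. Without their 50 most abundant genes 5 of the 6 libraries still stood apart, which were all 5 that deviate alike. The levels of those genes alone thus do not set these 5 apart. A correlation over 11314 genes depends little on 50 of them, so the test decides no more than that. Bee 223 moved from -7.58 to -5.48, and a few abundant genes may account for it. The share of counts in the 50 most abundant genes lay above the range of the other libraries in 4 of the 6. The share of reads in no gene lay outside the range of the other libraries in 3 of the 6, above it in bees 158 and 017 and below it in bee 223, which leaves an excess of reads outside annotated genes open for 158 and 017, and below the range of the others lay the mapped share in 3, the genes detected in 4 and the ambiguous share in 5, so that poor RNA or library quality stays open. A test of poor RNA in the 5 (2.35% of the other libraries had as high a share in no gene as the lowest of them) was dropped, since its threshold was chosen after an undecided result, and no biological explanation was tested, since the 6 fall into 5 groups of treatment, time and colony.

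The response to nurturance differed between 60 and 30 min for 947 genes, 866 of them lower at 60 min. Without the 6 libraries 2 genes differed, so that these libraries may account for most of the pattern. Of the 6, those at 60 min are control bees and those at 30 min nurturance bees. Their mean deviations correlated with 0.878 across genes, which are not independent replicates. This correlation follows from the shared deviations described above and is no separate support. A difference between the times is left open for the genes that still pass.

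Of the genes that rose over the mean of times, 22 were genes of high spread, and 18 of these still passed without the 6 libraries, which argues against those libraries as the cause. The nurturance bee had the higher mean level of the 22 genes in 68% of 75 pairs, but the genes were chosen from these bees, and with genes chosen without the colony tested the share was 61.3% (46 of 75, exact 95% interval 49.4 to 72.4%; 17 of 27 in R02, 18 of 24 in R40 and 11 of 24 in R41), so that a few bees with very high values stay open. In control bees the 22 genes varied together, with a median pairwise correlation of 0.434, against a median of 0.0736 and a 95th percentile of 0.124 over 10000 random sets of genes of high spread. Carry-over of another tissue in some dissections may give this, and shared regulation would give the same. Genes that vary together also tend to pass a contrast together, so such a set can exceed random sets whatever the cause. The correlation thus does not decide between these explanations. Markers of other tissues could not be matched to the identifiers, and a response to nurturance stays open.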

How the results depend on the processing

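The fits without the 6 libraries that stand apart, without each of them or bee 103, to paired bees without a block, and with a lane-label term were tests chosen only after the result was seen. Of 129 counts under alternatives 49 were within 1.5 times the real count and 80 were not, and of 308 fold changes of named genes 238 kept direction and side of the threshold, 70 kept the direction only and 0 reversed. The genes named for nurturance were chosen for the same sign in each colony, which makes a reversal unlikely. The cause of the moves was not tested. The 1 library under 0.5 of the median total, the shallow library below, is control bee 158. The fit without it and the fit without this bee are thus the same, and both are among these counts.
At 30 min the 17 genes became 11 without a filter, 7 by limma-voom, 47 by the Wald test of DESeq2, 5 and 6 with the replicate block (exact numbers, suffix dropped), 6 for the bees of exact pairs without a block, 8 with the random effect in limma-voom, 1, 0 and 67 without colonies R02, R40 and R41 (394 at an unadjusted p under 0.05 for R40), 70 in single-lane and 0 in merged-lane libraries (378), 76 without the 1 library under 0.5 of the median total, 8 with 2 surrogate variables and 8 with bees of that time alone. At 60 min the 66 became 38, 28 and 126 in the same first 3 settings, 2 and 22 with the replicate block, 2 and 100 for the same bees without it, 32 with the random effect in limma-voom, 6, 153 and 5 without the colonies, 6 and 17 by lane label, 22 without the shallow library and 14 with bees of that time alone. At 120 min the 6 became 0 by limma-voom (468), 22 by DESeq2, 0 and 0 with the replicate block (532 and 452), 2 for the bees of exact pairs without it, 0 with the random effect in limma-voom (512), 0, 0 and 0 without the colonies (297, 531 and 351), 2 and 0 by lane label (388 in merged-lane), 16 without the shallow library, 13 with surrogate variables and 3 without the 6 libraries. For the mean of times the 72 became 40 by limma-voom, 20 and 46 with the replicate block, 35 for the bees of exact pairs without it, 45 with the random effect in limma-voom, 17 and 13 without R02 and R40, 17 and 0 by lane label (359 in merged-lane), 119 with surrogate variables and 118 without the 6 libraries. The replicate block changed no call on GB40074 (30 min, 60 min and mean of times), GB49295 (mean of times), GB49756 (30 min) and GB42534 (60 min). The within-pair correlation of the random effect was 0.0534.
Without single libraries the counts ran from 6 to 76 at 30 min, from 22 to 476 at 60 min, from 1 to 16 at 120 min and from 61 to 90 for the mean of times. Genes whose response differed between times went from 10 to 2 by limma-voom and 1 without the 6 libraries, and between colonies from 1 to 0 by limma-voom (248). Genes differing between times in control bees went from 86 to 131 with the size factors of DESeq2, 52 without a filter, 30 by limma-voom and 299 without the 6 libraries, and between colonies from 5444 to 3274 with the lane-label term. That term rests on the bees of R02 at 120 min alone. Single-lane libraries hold no bee of R41, so that their count of 2697 is for R02 against R40 alone, where all libraries gave 3245. At 30 and 60 min the merged-lane libraries are those of R41 alone. The 2 genes related to time in the queen cell became 0 by limma-voom (357), with log2 of the time (810) and without the 2 longest times (1538), and 0 without bee 103 (526). Tests of gene lists, with their alternatives, were not run. In counts simulated at these depths and numbers of bees, which were not varied apart, small changes were often missed. Of genes simulated with the smallest change 56, 50 and 54% were recovered at 30, 60 and 120 min. The simulated spread followed abundance alone, so the shares in these bees may differ.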

Other observations

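The tests of colony sharing, of absent genes, of modules and of the genes related to time in the queen cell were chosen only after the result was seen. Whether the colonies share a response was asked of genes called in the other colonies. Genes that passed in a contrast over 2 colonies, taken from the fit to all bees, had the same sign in the colony left out in 88.4% of cases: 14 of 15 for R02, 19 of 19 for R40 and 43 of 52 for R41, and without the 6 libraries that stand apart 43 of 44, 33 of 41 and 78 of 83. Over all genes the fold changes of the colony left out correlated with those of the other two by 0.358 for R02, 0.362 for R40 and 0.295 for R41. An effect shared by the colonies is consistent with the share among these called genes, as a hypothesis.

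In control bees 2 genes had no read in any bee of a colony and a mean of at least 1 CPM in another, GB43063 in R02 and R41 and GB42575 in R40, named after their values were seen. Both separate R02 from R40, that is 100% of such genes, which argues against the lane label as the cause. Nurturance bee 103 at 60 min, labelled R40, had 4.97 CPM of GB55143, and its correlation with R40 over 200 colony genes minus that with R02 was -0.968. Its control partner resembled R40 with 0.897, and none of the other 175 bees was out of place, so that a single wrong label, or a bee that came from another colony, may explain it. Without this bee 0 of the 2 genes related to time in the queen cell passed (526 at an unadjusted p under 0.05), so that a bee or label of another colony may account for that relation.

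Genes of high spread formed 6 modules of 25, 24, 23, 19, 17 and 10 genes that varied together between control bees, and 11 of the genes that rose lay in each of the first and the third. No module differed between nurturance and control bees past an adjusted p of 0.05 in 24 permutation tests of 100000 resamples within pairs. The lowest, for the first module at 120 min, was a log2 difference of 0.96 with p = 0.004 and an adjusted p of 0.096. Over the mean of times the first module was higher in nurturance bees by 0.45 (p = 0.034, adjusted p = 0.21) and the third by 0.67 (p = 0.013, adjusted p = 0.16). The hypothesis that nurturance moves a whole module is left open by these values.

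Bees were regrouped at random, with treatment swapped within pairs (within time and colony for unpaired bees), pairs moved between times or between colonies, or times in the queen cell shuffled within groups, and the regroupings that gave as many genes were counted with the real one included. For nurturance against control chance was excluded at this share at 60 min (1 of 60, 66 genes against 11 in the highest other) and for the mean of times (1 of 60, 72 against 30). At 30 min 2 of 60 gave as many (17 against 18), a share under 0.05. The first 40 also held 2, a share of 0.05 at which chance is not excluded. More were drawn after this was seen, so the regroupings do not decide at 30 min. At 120 min chance was not excluded (7 of 60, 6 against 21). Without the 6 libraries that stand apart 2 of 80 gave as many at 30 min (12 against 24), 1 of 80 at 60 min (55 against 13), 3 of 80 at 120 min (3 against 3) and 1 of 80 for the mean (118 against 11). In control bees 1 of 80 did for times (86 against 36) and 1 of 100 for colonies (5444 against 27). For time in the queen cell 18 of 100 did, and the highest other called 1219 genes, many times the real count of 2. The source of such high counts was not tested. The numbers of regroupings were set by run time after 40 and then 60 to 100 had been drawn and seen.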
